A study of Drosophila melanogaster with 4 samples.

How the data were processed

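RNA of pharate adults, flies complete in form but still inside the pupal case, was measured in 4 lines of Drosophila melanogaster with 1 library per line. Per the labels' protocols, flies were raised on cornmeal food at 24 °C, total RNA was depleted of ribosomal RNA and treated with DNase, libraries were made with the TruSeq kit, and paired-end reads of 48 nt were taken on an Illumina HiSeq instrument. The submitters' processing notes name TopHat, SAMtools, bedtools and Cufflinks without versions and the genome build dm3. The annotation, the treatment of reads that map to several places, the use of strand and the number of reads per library are not given in the sources used here.

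The deposited values are FPKM, fragment counts scaled to transcript length and sequencing depth, computed by the authors and headed as FPKM in the files. There is 1 value per locus and library for the same 13866 loci in all 4 libraries. The column of the LU.10580/CAG library is headed het, and the other columns are headed hom, tg1 and tg2. Of the loci, 12066 carried a single gene name, 944 carried several names joined together and 856 carried no name. Among all loci, 3 carried names that a spreadsheet had turned into dates. Loci where hom lay lowest relative to the other 3 libraries came first in the files. Across 13415 loci, place in the file and the gap of hom below the mean of the others, divided by the standard deviation, had a Spearman correlation of −0.9999. That ordering was not used in any step.

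Names were matched to the gene symbols and synonyms of a Release 6 annotation, which gave names and gene types only. All coordinates are those of the deposited dm3 loci, counted from 1. Of the single names, 11834 matched and 11463 of these were protein-coding. A synonym counted only where it belonged to a single gene; this rule was tightened after wrong matches had been seen. A locus span of the files can cover several genes, and genes that overlap or share near-identical copies can share fragments, so values of such genes are uncertain.

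Differences between libraries were taken on the log2(FPKM + 1) scale, which understates the change of loci with low values, and folds are given on the same FPKM + 1 scale. Loci with a mean of at least 1 FPKM over the 4 libraries were tested, which left 11689, among them 9667 protein-coding loci. A locus was called where the difference was at least 1, a 2-fold difference. With 1 library per line there is no replicate spread, so no p-value was computed and no difference has a replicate check. A library stood apart at a locus where it lay at least 1 above or at least 1 below each of the other 3 libraries. The 4 values were permuted within each locus 100 times. This gave the correlation of tg1 against hom with tg2 against hom for libraries that are interchangeable, with hom shared. Values peculiar to hom are spread over all libraries by permutation, so the hom library alone can give more than this level. Gene lists were described by the median difference of their tested members and its percentile among 10000 random lists of the same size and like mean expression. Random lists hold unrelated loci, so a list whose genes vary together can lie outside them with a small shift. The percentile describes these libraries and does not measure whether a difference would recur. Shares per chromosome arm carry exact Clopper-Pearson 95% intervals over loci, which cover counting error only.

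The call, the filter, the lists, the comparisons and the rule for named genes were chosen before the data were examined. That rule took the 10 largest differences per direction in each pair of lines, the 10 loci per direction that stood farthest apart in each library, and for each list the extreme and the most abundant members. Most loci it took were small RNA loci or loci listed at 0 in a library. A ranking of protein-coding loci with a single matched name and no value of 0 was therefore added after the data had been seen, and most genes named in the text come from it or from the lists. The summaries by symbol group, the comparison of line pairs with each other and the genes around the 2R cluster were also chosen after seeing the data.

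A value of 0 in these files can be a failed estimate. The proteasome gene Prosalpha1 was listed at 0 in all 4 libraries, and 401 loci were. Such loci are described as listed at 0, with no fold. Of the tested loci, 146 had a 0 in at least 1 library. The total depth of the libraries is unknown. Steps between the lowest values gave the depth relative to CAG as 0.766 for hom, 1.12 for tg1 and 1.15 for tg2; these are the most frequent ratios among 237, 283 and 278 low loci, of which 69, 48 and 73 lay within 3% of that ratio. No count test was run.

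Alternatives were a pseudocount of 0.1 or 5, no filter, a filter of 5 FPKM, centring of each library on its median, scaling by a trimmed mean, and leaving out the chromosome arm with the largest share of calls. Leaving out loci listed at 0 and keeping only protein-coding loci were added after seeing the data. The steps were tested on simulated data of 11689 loci with a noise SD of 0.2 on the log2 scale. For hom against CAG, 1 of 50 loci with a true 1.5-fold difference, 44 of 50 with a 3-fold and 50 of 50 with an 8-fold difference were called. Of 11489 loci without a difference, 2 were called. For hom against all 3 other lines, 38 of 50 loci with a 3-fold difference were called. The simulated noise was the same at all abundances, without values of 0, and no replicates were there to set it. In the data the differences of hom from CAG had an SD of 0.74 over all tested loci. The simulation checks the steps and does not give the rate of false calls in the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The sequencing reads, and with them the chimeric reads named in the series title, were not analysed here.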

Results

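Gene expression was compared between 4 Drosophila lines at the pharate adult stage, called CAG, hom, tg1 and tg2 after the ends of the line names LU.10580/CAG, LU.10580hom, LU.10580.tg1 and LU.10580.tg2. What these names stand for is not given in the sources used here, and neither are the sex or the exact age of the animals. The series title names chimeric reads as its subject, and the deposited values give expression per locus. Each line had 1 library, so every difference is a difference between libraries without a replicate check. Between 11380 and 11659 loci per library had at least 1 FPKM, and the median over all loci was 8.48 FPKM in CAG, 8.14 in hom, 8.05 in tg1 and 8.38 in tg2. The most abundant locus held 30.2% of the FPKM sum in CAG, 30.4% in hom, 17.5% in tg1 and 14.9% in tg2. The depth of hom relative to CAG was 0.766, the lowest of the 4, so a low value in hom rests on fewer fragments.

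Among protein-coding genes, immune peptides, seminal fluid genes and storage proteins differed between hom and CAG. Loci of the Bomanin cluster, which encode short secreted peptides of the Toll immune response, were lower in hom, and the antimicrobial peptides Dpt (diptericin), Dro (drosocin) and Mtk (metchnikowin) were higher. Seminal fluid genes were lower in hom than in CAG, and 3 of 4 larval serum proteins, the hexamerins that larvae store for metamorphosis, were higher. Among all tested loci 219 were called higher in hom and 401 lower. Among protein-coding loci with no value of 0 there were 143 higher and 257 lower. The values of the 2 libraries had a Pearson correlation of 0.935 over all tested loci and 0.964 over these protein-coding loci, across loci that are not independent replicates.

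The tested loci of the Bomanin cluster lie side by side on chromosome 2R between 14271457 and 14278114. Just before them lie members below the filter. CG42737 (BomT1) had 2.88 FPKM in CAG and was listed at 0 in hom, tg1 and tg2, and IM23 (BomBc1) was listed at 0 in all 4 libraries. CG15067 (BomBc2) stood at 77.9 FPKM in CAG, 1.68 in hom, 62.0 in tg1 and 44.4 in tg2, a difference of −4.88 between hom and CAG. CG18107 (BomS4) stood at 91.8 FPKM in CAG, 5.93 in hom, 64.2 in tg1 and 68.3 in tg2. CG15068 (BomS6), the most abundant member, stood at 725 FPKM in CAG, 81.9 in hom, 628 in tg1 and 526 in tg2. IM3 (BomS3) had 117 FPKM in CAG, 4.88 in hom, 40.6 in tg1 and 30.2 in tg2. CG16836 (BomT2) had 21.0, 0.874, 5.10 and 5.90 FPKM in the same order, and IM1 (BomS1) had 15.6, 3.01, 10.8 and 8.95. IM2 (BomS2) was listed at 0 in hom and had 79.1 FPKM in CAG, 37.3 in tg1 and 11.7 in tg2. CG15065 (BomS5) was listed at 0 in hom with 9.11 FPKM in CAG, 1.58 in tg1 and 6.28 in tg2. IM2, IM3 and CG16836 were thus at least 2-fold below CAG in tg1 and tg2 as well, and so was CG15065 in tg1. The next gene on the chromosome, Idgf5, a chitinase-like growth factor at 2R:14281170 to 14282787, had 37.1 FPKM in CAG and 57.8 in hom. IM14 (Dso2), an immune-induced peptide gene outside the cluster at 2R:16757930 to 16758134, had 186 FPKM in CAG, 75.6 in hom, 214 in tg1 and 145 in tg2.

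**Figure D1:**
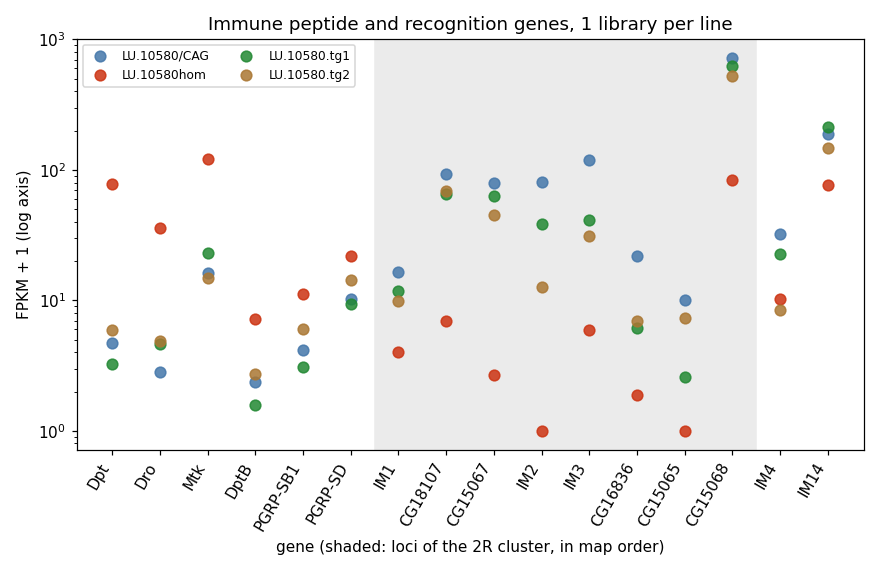
FPKM + 1 on a log axis for 16 immune loci, 1 point per line and locus, with the tested loci of the Bomanin cluster of 2R shaded in map order. In the shaded part hom is the lowest point at every locus, and at Dpt, Dro, Mtk, DptB, PGRP-SB1 and PGRP-SD hom is the highest.

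Dpt had 76.3 FPKM in hom against 3.68 in CAG, 2.25 in tg1 and 4.96 in tg2. Dro had 34.9 FPKM in hom against 1.84, 3.64 and 3.87, and Mtk had 119.8 against 15.3, 21.9 and 13.7 at 1 of its 2 loci. The other Mtk locus, with the same span, had 4.001 FPKM in hom and 5.34 in CAG. DptB, a second diptericin, had 6.21 FPKM in hom and 1.35 in CAG. PGRP-SB1 and PGRP-SD, peptidoglycan recognition proteins, had 10.2 and 20.8 FPKM in hom against 3.14 and 9.31 in CAG. Drosomycin (Drs), an antifungal peptide, differed by 0.67 on the log2 scale, short of the call. Over the 23 tested loci of the antimicrobial list 6 were called higher and 5 lower in hom than in CAG. Of the tested Bomanin loci this list held only IM1, IM2 and IM3, because the others carry CG names that the list did not include. The list median was 0.61, at percentile 100 of the random lists, with members on both sides. It does not describe the Bomanin cluster, whose tested loci had a median of −3.65.

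Several storage protein genes had their highest values in hom, and so did some single genes of secreted proteins. Lsp1alpha had 1059.9 FPKM in hom and 193 in CAG, Lsp1beta 1788 and 491, and Lsp2 3105 and 1413, while Lsp1gamma, with 718 and 662, was short of the call. Fbp1, the receptor that takes hexamerins up into the fat body, had 2460.2 FPKM in hom and 914 in CAG, and the odorant-binding protein gene Obp99b had 2507 and 622. Of the 15 tested loci of the larval serum and fat body list 5 were called higher in hom and 0 lower, with a median of 0.32 at percentile 99.98. The predicted serine proteases CG18180 and CG18179, which share the span 3L:9624934 to 9674160, had 1309.9 and 155 FPKM in hom against 15.0 and 1.27 in CAG. Fragments of these neighbours can be shared, so the split between them is uncertain. The lysozyme gene LysX had 149.8 FPKM in hom and 5.88 in CAG, while its neighbour LysD had 5.88 in hom and 28.0 in CAG. Ag5r2, of the antigen 5 family of secreted proteins, had 75.9 FPKM in hom and 2.65 in CAG, and CG42397 had 350.3 and 6.65. These single genes did not extend to the gut digestion list, whose median was −0.37 at percentile 1.5 with 0 of 9 loci called higher in hom and 1 lower.

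Seminal fluid genes separated hom from CAG in the other direction. In the male accessory gland list 13 of 14 tested loci were called lower in hom than in CAG and 0 higher, with a median of −2.23 at percentile 0. Acp70A, the sex peptide that alters female behaviour after mating, had 96.2 FPKM in CAG and 19.1 in hom. Acp95EF had 500.0 FPKM in CAG and 77.8 in hom, and Dup99B, a sex peptide relative made in the ejaculatory duct, had 88.6 and 11.5. Acp98AB was listed at 0 in hom with 159.8 FPKM in CAG. The testis list as a whole did not share this difference, with a median of 0.01 over 18 loci. Its only 2 called members, Mst57Da and Mst57Db, went the way of the accessory gland list and apart from the rest of the testis list. They had 108 and 212 FPKM in CAG against 25.9 and 23.6 in hom. The RNAs roX1 and roX2, which mark male dosage compensation, had 190.5 and 548 FPKM in CAG and 229 and 677 in hom.

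Photoreceptor and neuronal genes were a little lower in hom. The photoreceptor list had a median of −0.30 over 23 loci, at percentile 0, and the neuron list a median of −0.42 over 13 loci, at percentile 0, with 0 of the 13 past the call. Rh5, the blue-sensitive opsin of a class of inner photoreceptors, was the only photoreceptor locus past the call, with 19.7 FPKM in CAG and 1.28 in hom. norpA, the phospholipase C of phototransduction, had 47.4 and 30.1 FPKM, and the sodium channel gene para had 23.1 and 14.3. Cuticle protein genes lay on the other side, with a median of 0.36 over 71 loci, 13 called higher in hom and 1 lower. The list was taken by symbol and includes Cpr, a cytochrome P450 reductase, and its median was also 0.36 over the 70 loci without it. Cpr49Ac had 23.7 FPKM in CAG and 79.7 in hom, and Lcp65Ac had 2.54 and 13.9. Germline genes had a median of −0.44 over 13 loci, and osk, which assembles germ plasm in the egg, had 6.22 FPKM in CAG and 0.851 in hom.

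The comparison of tg1 with hom gave 213 loci higher in tg1 and 201 lower, and 122 and 122 among protein-coding loci with no value of 0. The tested loci of the Bomanin cluster were higher in tg1 than in hom. CG15067 was 23.5-fold, CG15068 7.59-fold and IM1 2.95-fold higher on the FPKM + 1 scale. Of the serum proteins, Lsp1alpha had 51.1 FPKM in tg1 against 1059.9 in hom, a difference of −4.35, and Lsp1gamma differed by −0.86, short of the call. The larval serum and fat body list had a median of −0.58 with 0 of 15 loci called higher and 5 lower, and LysX, CG18180 and Ag5r2 differed by −3.91, −4.01 and −3.09. Photoreceptor genes had a median of 0.39 and neuronal genes a median of 0.50, both at percentile 100. Accessory gland genes had a median of 0.69 with 4 of 14 loci called higher, and Acp62F had 62.7 FPKM in tg1 and 30.6 in hom. Under a pseudocount of 5 the balance of calls was 74 higher and 107 lower.

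Among named protein-coding loci with no value of 0, the gene furthest above hom in tg1 was Oaz, a zinc-finger protein gene at 2R:10323623 to 10353376. Oaz had 34.2 FPKM in tg1 and 0.294 in hom, 0.268 in CAG and 0.185 in tg2. Its neighbour phyl, at 2R:10314841 to 10319840, had 2.32 FPKM in tg1 and 1.88 in hom. bun, a TSC-22 family regulator of growth at 2L:12455538 to 12546630, had 36.3 FPKM in tg1 and 5.25 in hom at 1 of its 2 loci, and 113.0 and 109.7 at the other. CG14059 (Ilp8), the insulin-like peptide that delays metamorphosis when tissues are damaged, had 9.01 FPKM in tg1 and 1.01 in hom. The broad gene br, an early ecdysone response regulator, had 4.25 FPKM in tg1 and 9.78 in hom.

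The comparison of tg2 with hom gave the most calls of the 4 planned pairs, with 442 loci higher in tg2 and 315 lower, and 245 and 213 among protein-coding loci with no value of 0. Loci without a gene name contributed 131 of the higher and 45 of the lower calls, from 722 such loci with a median of 0.39. The tested loci of the Bomanin cluster were again higher than in hom. CG15067 was 16.9-fold, CG15068 6.36-fold and IM1 2.48-fold higher on the FPKM + 1 scale. Germline genes had a median of 0.72 at percentile 99.99 with 5 of 13 loci called higher, among them piwi, which guards germ cells against transposons, with 5.65 FPKM in tg2 and 1.31 in hom. vas, a germline RNA helicase, had 3.40 FPKM in tg2 and 0.927 in hom. Neuronal genes had a median of 0.59 with 4 of 13 loci called higher, and Snap25, a protein of synaptic vesicle fusion, had 125 FPKM in tg2 and 57.5 in hom. The testis list had a median of 0.47 at percentile 100 with no locus past the call, and dj, a sperm tail gene, had 194 and 102 FPKM.

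Some loci of serum proteins, cuticle proteins, heat shock proteins and detoxification enzymes were called lower in tg2 than in hom. The larval serum and fat body list had a median of −0.89 with 7 of 15 loci called lower and 0 higher, the cuticle list −0.52 with 18 of 71 lower and 2 higher, and the heat shock list −0.57 with 4 of 13 lower and 0 higher. Hsp23, a small heat shock protein, had 262 FPKM in tg2 and 705 in hom, while Hsp67Bc lay the other way with 28.2 and 18.7. Hsp23 had 382 FPKM in CAG and 333 in tg1, and tg1 was also called lower than hom, by −1.08. In the detoxification list 12 of 66 loci were called lower and 2 higher, and GstD10, a glutathione transferase, had 1.13 FPKM in tg2 and 9.45 in hom. GstD10 had 2.36 FPKM in CAG and 1.27 in tg1, and tg1 was called lower than hom by −2.20. At Hsp23 and GstD10 hom was thus the highest line, and the low value was not particular to tg2. The Turandot stress peptides had a median of −0.83 over 7 loci, with 3 called lower and 1 higher. The ribosomal protein list of 74 loci had a median of −0.23 at percentile 0, and its 1 call, RpS5b, was higher in tg2 with 29.8 FPKM against 14.3.

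The differences of tg1 and tg2 from hom went together across loci, with a Pearson correlation of 0.58 and a Spearman correlation of 0.63. Permuting the 4 values within each locus, which keeps the shared hom library, gave 0.50 and 0.46. The covariance was 0.287 against 0.237 under permutation, a difference of 0.0494. There were 133 loci called higher in both and 130 called lower in both. Permutation gave means of 90.8 and 106, and independent lists of these lengths would share 8.05 and 5.42. Part or all of the overlap can come from the single hom library that both differences contain. Permutation does not keep values peculiar to hom in hom, so it sets no upper limit on that part.

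tg1 and tg2 differed from each other at 156 loci called higher in tg1 and 231 lower, and at 80 and 88 protein-coding loci with no value of 0. Adh, the alcohol dehydrogenase at 2L:14599776 to 14689405, had 238 FPKM in tg2 against 764 in tg1, 682 in CAG and 655.0 in hom. Npc1a, a sterol transport protein gene at 2L:10213820 to 10220957, had 12.01 FPKM in tg2 against 54.1, 52.3 and 50.8. nimC1, a receptor by which blood cells take up bacteria, at 2L:13974117 to 13976753, had 2.11 FPKM in tg2 against 17.9, 17.6 and 15.4. He (Hemese), a blood cell surface protein gene at 2L:13970529 to 13972947, was higher in tg2, with 4.49 FPKM against 1.18 in tg1. proPO-A1, a phenoloxidase of blood cells, had 1.79 FPKM in tg2 and 7.07 in tg1, and the scavenger receptor gene Sr-CI had 5.52 and 13.2. Of the 12 tested loci of the hemocyte list 3 were called higher in tg1 and 1 lower, with a median of 0.28 at percentile 99.91, and Hml had 57.5 FPKM in tg2 and 74.0 in tg1. Lectin-galC1, a galactose-binding lectin on 2L, had 84.9 FPKM in tg2 and 313 in tg1.

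Arm 2L held 60 of the 166 protein-coding calls between tg1 and tg2, 36.1%, and 19.2% of the protein-coding loci tested. For hom against CAG the share on 2L was 19.6%, for tg1 against hom 13.2% and for tg2 against hom 22.6%. Of 50 protein-coding loci on the main arms at which tg2 stood apart by 1 or more, 21 lay on 2L, which is 42% with a 95% interval of 28.2% to 56.8%. Of 306 such loci with a gap of 0.5 to 1 in tg2, 96 lay on 2L, 31.4% with an interval of 26.2% to 36.9%. The corresponding shares on 2L with a gap of 0.5 to 1 were 22.2% in CAG, 14.4% in hom and 14.0% in tg1. Other lines had an excess on other arms. In tg1 31 of 93 loci with a gap of 0.5 to 1 lay on 2R, 33.3% with an interval of 23.9% to 43.9%, against 19.9% of tested loci, and 2R held 30.2% of the calls of tg1 against hom. In CAG 30.9% of loci with a gap of 1 or more lay on 3L, with an interval of 21.1% to 42.1%, against 19.6% of tested loci. With a gap of 0.5 to 1 the share of 3L in CAG was 19.3%, which is no excess. In that band 2R held 26.7% in CAG, with an interval of 20.3% to 33.9%. For hom 29.3% in that band lay on 3R, with an interval of 24.6% to 34.4%, against 24.2% of tested loci. In tg2 the highest share along 2L was between 8 and 12 Mb, where 34 of 400 tested loci stood apart by at least 0.5. Between 0 and 4 Mb of 2L there were 11 of 352, and between 4 and 8 Mb of 2R 26 of 372. Without the calls on 2L the count of loci higher in tg1 than in tg2 was 95.

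**Figure D2:**
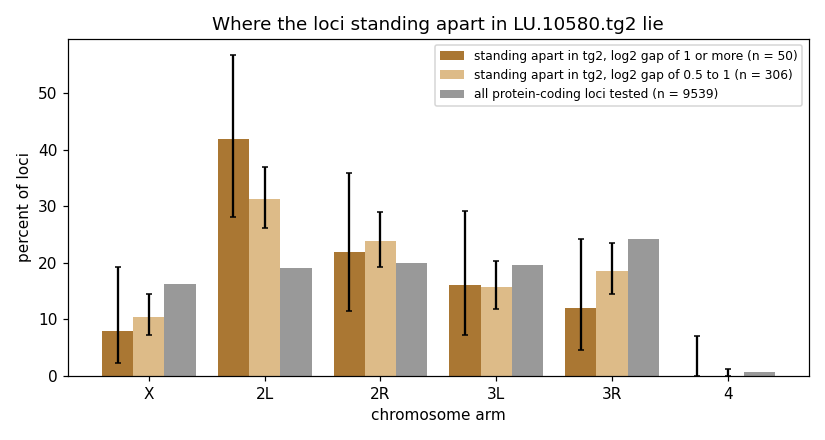
Share of protein-coding loci per chromosome arm, in percent, for loci standing apart in tg2 by at least 1, by 0.5 to 1 and for all loci tested, with exact 95% intervals over loci. On 2L the bars stand at 42% and 31.4% against 19.2% of tested loci.

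Loci at which a single library stood at least 2-fold apart from each of the other 3 were counted for all lines. hom stood above at 80 loci and below at 87, CAG at 91 and 41, tg2 at 77 and 59, and tg1 at 13 and 21. Among protein-coding loci with no value of 0 the counts were 54 and 54 for hom, 54 and 27 for CAG, 19 and 32 for tg2, and 4 and 5 for tg1.

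Seminal fluid genes were a part of the 91 loci at which CAG stood above the other lines. Of 22 tested loci with a seminal fluid symbol (Sfp), CAG stood above all 3 other lines at 11 and below at 0, and of 11 accessory gland loci (Acp) it stood above at 5. Sfp87B had 106 FPKM in CAG against 4.02 in hom, 8.34 in tg1 and 6.93 in tg2, and Sfp24Bb had 60.3 against 4.33, 4.67 and 3.59. PebII, an ejaculatory bulb protein gene, had 55.2 FPKM in CAG against 4.80, 6.19 and 2.72. Sfp36F was listed at 0 in the other 3 lines and had 104.7 FPKM in CAG. The Osiris genes, a family of membrane proteins clustered on 3R, were low in CAG at 4 of 9 tested loci. Osi20 had 4.43 FPKM in CAG against 39.5 in hom, 78.0 in tg1 and 63.2 in tg2, and Osi15 had 8.67 against 61.4, 98.0 and 85.6.

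hom stood above the other lines at 3 of 4 tested larval serum protein loci and below them at the tested loci of the Bomanin cluster and 1 locus of bun. At seminal fluid loci it stood below at 1 of 22 and above at 0. CG14059 (Ilp8) at 1.01 FPKM and CG5162 at 2.09 FPKM were below all 3 other lines. tg1 stood above at the protein-coding loci Oaz, Nplp4, CG7544 and a minor locus of RpS3A with 3.02 FPKM, and below at CG2444, CG4213, Sfp33A1, CG42857 and CG13426. Nplp4, a neuropeptide-like precursor gene, had 7.33 FPKM in tg1 against 2.05 in CAG, 2.16 in hom and 1.42 in tg2. In tg2 the largest gap above at a named protein-coding locus was at phr, the photolyase that repairs ultraviolet damage, at 2R:3712997 to 3716181. phr had 17.8 FPKM in tg2 against 1.10 in CAG, 1.29 in hom and 1.06 in tg1. The files give the same span to Prosalpha1, which was listed at 0 in all 4 libraries. AttD, an antibacterial peptide gene, had 4.06 FPKM in tg2 against 0.166, 0.219 and 0.570 in CAG, hom and tg1, and CG42872 (MtnE), a metallothionein, had 45.6 against 16.2, 10.4 and 16.8.

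**Figure D3:**
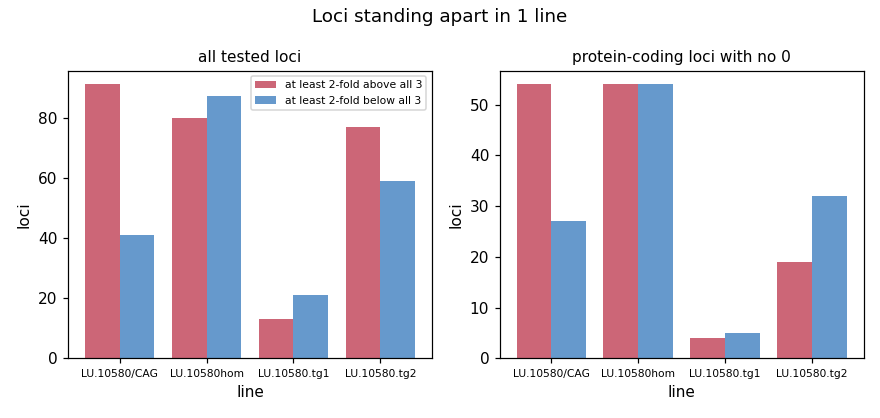
Number of loci at which each line stood at least 2-fold above or below all 3 other lines, for all 11689 tested loci and for 9627 protein-coding loci with no value of 0. tg1 has the fewest, with 4 above and 5 below among protein-coding loci.

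By the rule on size, most of the largest pair differences were at small RNA loci, and most rested on a value of 0. Small nucleolar RNAs, guides of ribosomal RNA modification, were among these loci and were not counted on their own. In the comparison of hom with CAG all 10 loci with the lowest values in hom were small RNA loci and were listed at 0. snoRNA:Me18S-A1806 on 3L was listed at 0 in hom and had 3744 FPKM in CAG, 3708 in tg1 and 2922 in tg2. Long genes were affected as well. fax, an axon guidance gene, was listed at 0 in hom with 56.3, 54.9 and 58.6 FPKM in CAG, tg1 and tg2, and bt, which encodes the giant muscle protein projectin, was listed at 0 in CAG and hom with 496 FPKM in tg1 and 504 in tg2.

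Across the 33 lists with tested members, medians lay outside the central 95% of random lists for 13, 14, 15 and 11 lists in the 4 pairs. These counts give no number of affected lists, since genes of a list can vary together and those of random lists are unrelated. Muscle genes had medians of −0.17, 0.16, 0.01 and 0.17 for hom against CAG, tg1 against hom, tg2 against hom and tg1 against tg2. For eye pigment genes the medians were 0.02, −0.07, −0.02 and 0.04, and for cuticle tanning genes −0.02, 0.04, −0.02 and 0.17. Spliceosome genes had medians of −0.09, 0.03, 0.04 and 0.00, and nonsense decay genes −0.05, 0.02, 0.04 and −0.06. Genes known for trans-splicing, in which exons of separate transcripts are joined, had −0.08, 0.01, 0.08 and −0.18. In that list the most abundant mod(mdg4) locus had 33.3 FPKM in CAG, 32.4 in hom, 30.5 in tg1 and 30.4 in tg2, and lola had 96.2, 87.3, 90.8 and 99.3. Genes of RNA ligation and tRNA processing had 0.14, −0.03, −0.26 and 0.08, with 0 of 7 loci past the call in any pair.

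**Figure D4:**
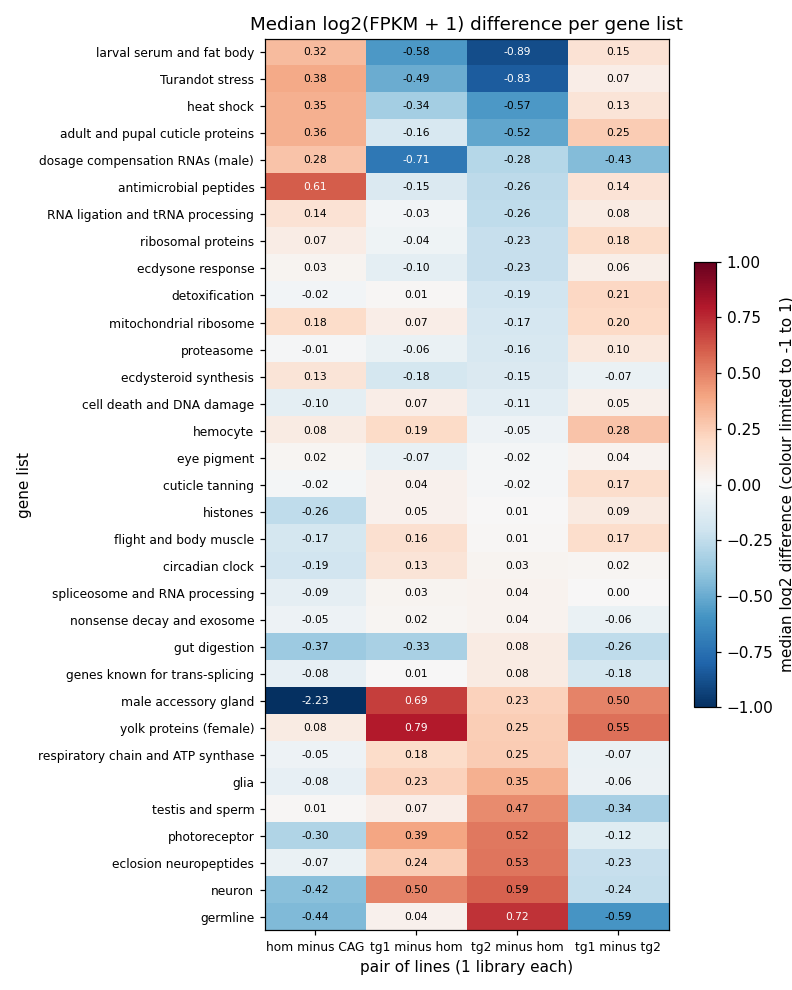
Median log2(FPKM + 1) difference of each gene list (vertical axis) in the 4 pairs of lines (horizontal axis), with colours limited to −1 to 1. The accessory gland list at −2.23 for hom against CAG lies beyond the colour range, and larval serum genes stand at −0.89 for tg2 against hom.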

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

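Counts and list medians were recomputed under other settings, and a count is given here where it differed by more than 1.5-fold. Under a pseudocount of 5, hom against CAG gave 112 higher and 189 lower in place of 219 and 401. With the same pseudocount tg1 against hom gave 74 and 107 in place of 213 and 201, tg2 against hom 175 and 166 in place of 442 and 315, and tg1 against tg2 72 and 88 in place of 156 and 231. It left hom above the other 3 lines at 49 loci and below at 32, CAG at 55 and 18, tg1 at 8 and 11, and tg2 at 33 and 28. In the main setting these were 80 and 87 for hom, 91 and 41 for CAG, 13 and 21 for tg1, and 77 and 59 for tg2. A pseudocount of 0.1 gave 382 higher and 317 lower for tg1 against hom, 691 higher for tg2 against hom, and 238 and 384 for tg1 against tg2. It placed hom below at 179 loci, CAG below at 74, tg1 above at 27 and below at 64, and tg2 below at 100.

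A threshold of 5 FPKM gave 144 higher and 233 lower for hom against CAG, 129 and 129 for tg1 against hom, 254 higher for tg2 against hom and 110 lower for tg1 against tg2. It left CAG above at 51 loci and tg2 above at 35. Median centring, a trimmed mean and no expression filter left all 16 counts within 1.5-fold. Of 132 list medians 21 moved under a pseudocount of 5, 6 under a pseudocount of 0.1, 13 with no filter, and 0 under centring or the trimmed mean. With the threshold of 5 FPKM 18 of 128 moved. Leaving out 1 arm gave hom below at 57 loci without 2R, CAG below at 27 without 3L, tg1 above at 8 without 2R, tg2 below at 32 without 2L, and 95 loci higher in tg1 than in tg2 without 2L.

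The settings in this paragraph, and all settings for CAG, tg1 and tg2 standing apart, were added after the data were seen. Protein-coding loci with no value of 0 gave 143 higher and 257 lower for hom against CAG, 122 and 122 for tg1 against hom, 245 higher for tg2 against hom, and 80 and 88 for tg1 against tg2. They left hom below at 54 loci, CAG above at 54 and below at 27, tg1 at 4 and 5, and tg2 at 19 and 32. Leaving out loci with a value of 0 gave tg1 above at 7 loci and below at 13, and tg2 above at 45. The correlation of the differences of tg1 and tg2 from hom was 0.582, with 0.671 without loci at 0 and 0.709 over protein-coding loci. The cause was not tested. The alternative that asked for separate confidence intervals was not run, because the files used here give no intervals.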

Other observations

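Some genes had similar values in tg1 and tg2 and different values in CAG and hom. Cyp6a20, a cytochrome P450, had 91.0 FPKM in CAG, 79.1 in hom, 11.98 in tg1 and 13.2 in tg2. Oatp58Db, an organic anion transporter, had 11.5, 10.1, 0.914 and 1.01 FPKM in the same order. Oda, the antizyme that restrains ornithine decarboxylase, had 11.97, 11.5, 2.36 and 1.97, and Ctr1B, a copper transporter, had 6.54, 4.20, 1.06 and 1.08. CG42637 was higher in both, with 3.61, 1.77, 20.7 and 31.2. Among 9627 protein-coding loci, both tg lines stood at least 2-fold above the other lines at 8 and below them at 12.

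CAG and tg2 stood above hom and tg1 at 18 protein-coding loci and below them at 3, and CAG and tg1 stood above hom and tg2 at 3 and below them at 5. Nplp3, a neuropeptide-like precursor, had 229 FPKM in CAG, 18.9 in hom, 31.6 in tg1 and 103 in tg2. dhd, a thioredoxin of the female germline, had 21.3, 4.67, 3.69 and 11.7, and retinin, a protein of the corneal lens, had 32.3, 7.43, 13.03 and 27.5. These comparisons were chosen after the result was seen, and no biological explanation was tested.

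The Bomanin cluster was low in hom, all tests of this pattern were chosen after the result was seen, and no biological explanation was tested. The lowest difference of hom from CAG in the larval serum and fat body list was −0.19, which argues against a loss of fat body as a whole in the hom pool. The list mixes larval storage genes, several of them high in hom, with other fat body genes. It therefore cannot tell larval from adult fat body, and less adult fat body is left open. Of 10000 random sets of 8 loci of like abundance the lowest had a median of −0.75 against −3.65 for the cluster, which argues against lower depth of hom as the whole source, although an earlier test on single loci, with a central 95% of −1.13 to 0.87, had left it open. A sequence difference of the cluster may be present, and the genes outside it leave this open. IM14 was low in hom by −0.93 against the closest other line, while IM4 was 0.26 higher in hom than in tg2, with 9.17 and 7.47 FPKM.

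Loci standing apart in tg2 lay on 2L more than other loci, and both tests were chosen after the result was seen. Loci with a gap of 0.5 to 1, which did not give the pattern, lay on 2L in 31.4% of cases against 19.2% of tested loci, which argues against depth or scaling of tg2 as the whole source. The same value met the prediction for a left arm of chromosome 2 of other origin in tg2. It cannot single out that source, because other sources of uneven shares would meet the prediction too. The share of tested loci standing apart by at least 0.5 was 3.1% between 0 and 4 Mb of 2L and 8.5% between 8 and 12 Mb. Between 4 and 8 Mb of 2R it was 7.0%. The share was therefore uneven along 2L, and part of 2R reached a like level. An excess on another arm was also seen in each other line with a gap of 0.5 to 1. It was 33.3% on 2R in tg1 and 26.7% on 2R in CAG, against 19.9% of tested loci. In hom it was 29.3% on 3R, against 24.2% of tested loci. An excess on an arm is therefore not particular to tg2. Sequence variants were not used here, and no biological explanation was tested.

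Accessory gland genes were high in CAG, and both tests were chosen after the result was seen. For roX1, roX2 and the testis list the median of CAG against the mean of the other lines was −0.18. This argues against a larger share of males as the whole source. A modest difference in share is left open, since most of these loci are of the testis list and there is 1 library per line. roX1 had 190 FPKM in CAG, 229 in hom, 158 in tg1 and 206 in tg2, and roX2 had 548, 677, 364 and 508. A later stage of the CAG pool could raise these genes. The cuticle protein median was −0.17, and CAG stood below all other lines at 4 of 9 Osiris loci. These values cannot decide on stage, because no ages are given and the data do not show how the genes change with age. No biological explanation was tested.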
